A study of Homo sapiens with 22 samples.

How the data were processed

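Poly(A)-selected, strand-specific RNA sequencing was done on cultured human epidermal keratinocytes, per the labels' protocols. The 22 libraries fell into 8 groups by treatment and time as given in the labels: water, 2-PCPA (100 µM), DMSO and GSK-LSD1 (2 µM) for 2 days, dosed 2 times, with 3 libraries each; DMSO and GSK-LSD1 (2 µM) for 6 days, dosed 6 times, with 3 libraries each; and siCTL and siLSD1 (500 nM), harvested at 72 h, with 2 libraries each. Libraries of a group came from separate cultures, per the labels. The 4 arms at 2 days shared 3 cultures, and the 6 day and siRNA experiments used others. Both 6 day arms shared 3 cultures, and both siRNA arms shared 2. Whether the authors' tests used this pairing is not given in the sources used here. No control library was shared between tables.

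Reads were aligned with STAR 2.6.1 to hg19 and compared with DESeq2, per the submitters' processing notes. The counting tool, its strand setting, the annotation and the version of DESeq2 used by the authors are not given in the sources used here. For each of the 4 comparisons, treated against its own control, 1 table was used. The mean normalized count of each gene, a signal averaged over the libraries of both groups and not a raw count, was computed by the authors and deposited. The log2 fold change and its SE were fitted by the authors, per the file headers. The Wald score, which equalled the log2 fold change divided by its SE in the deposited tables, and the two-sided p-values with their Benjamini-Hochberg adjustment were also the authors'. The fitted level per group, a score deposited in the 6 day and siRNA tables, was the mean split by the fold change and held nothing further. Values per library were not used here, so no mean and SD per group, no refit and no pairing of cultures could be made. Genes that the authors marked as low had no adjusted p and were kept out of all counts. The numbers tested were 13954 of 26364 listed genes for GSK-LSD1 at 2 days, 13992 of 26364 for 2-PCPA, 15397 of 27914 for GSK-LSD1 at 6 days and 15136 of 27914 for siLSD1. The lowest mean among tested genes was 10.0 in both 2 day tables, 4.06 at 6 days and 10.9 for siLSD1. The precision can be read from the SE: at a mean of 1000 to 10000 its median was 0.10 at 6 days and 0.21 with siLSD1. The siLSD1 groups had fewer libraries, which alone would raise an SE by less than this.

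The deposited SE in both 2 day tables never exceeded 0.195 and 0.196 and became smaller again for genes of low mean, which is what shrinkage towards 0 with a normal prior gives. Prior SDs of 0.390 (GSK-LSD1) and 0.392 (2-PCPA) were computed from these maxima. A shrunken SE has 2 solutions for the unshrunken SE. The smaller was used for genes with a mean of at least 50, unless the deposited SE lay below 0.95 times the percentile 1 of the 301 genes of nearest mean (9 genes for GSK-LSD1 and 1 for 2-PCPA), and the larger otherwise. The median recovered SE at means of 100 to 500 was 0.20 and 0.18, against 0.22 in the unshrunken 6 day table. At means of 50 to 100 it was 0.35 and 0.32, against 0.40 at 6 days. The 2 solutions meet at the prior SD, which that 6 day value exceeds. The smaller solution may therefore be wrong for part of the genes at such means. Printed 2 day fold changes are the shrunken values as deposited, and recovered values entered only the differences between comparisons.

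The comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. A gene was called higher or lower at an adjusted p below 0.05 from the Wald test of DESeq2 run by the authors. Differences between 2 comparisons were tested as z, the difference of log2 fold changes over the root of the summed squared SEs, two-sided, with Benjamini-Hochberg adjustment over genes with a mean of at least 10 in both tables. This test treats the tables as independent, although the 2 day tables shared cultures. The planned test assumed unshrunken values. The scale on which it was run for the 2 differences with 2 day tables was chosen after the calls on 3 scales had been seen, so those 2 results are exploratory, and the other scales (values as deposited, and a gene passing only with both solutions) are given beside them. Shared calls were tested with the one-sided Fisher exact test, adjusted over 12 tests. The 28 gene lists were written from textbook knowledge. They covered epidermal differentiation (cornified envelope, spinous, fate transcription factors, lipid barrier, keratins), basal progenitor and adhesion genes, antimicrobial, interferon, antigen presentation, cell cycle, stress and signalling pathways, LSD1 complex and amine handling genes, and markers of neuronal, myeloid, melanocyte, fibroblast, endothelial, lymphoid and Merkel cells. Lists were tested with cameraPR on the Wald score with a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. An estimated correlation was not possible without values per library, so a preset 0.05 was the alternative.

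The genes named were KDM1A; per comparison the 8 higher and 8 lower called genes of largest log2 change with a mean of at least 50 and an absolute log2 change of at least 0.5, leaving out readthrough, noncoding, open reading frame and sex-linked marker symbols; up to 3 called members per list and direction with the lowest p; the 5 largest differences per direction under the same limits on mean (in both tables) and symbol; and up to 10 genes per direction shared by all 4 comparisons. GCOM1 and HTD2 were first left out as overlapping genes and then restored, since the rule names symbols only. For checks of GC content and length, transcripts of GENCODE release 29 were matched by symbol and older symbols, and between 96.6% and 97.5% of tested genes matched. Running-median trends of log2 fold change on GC content and on log2 transcript length were removed and p-values recomputed from the corrected change and the same SE. A wider edge than 0.95 was tried first. This correction, the added scales and the checks on exon overlap and on large SEs were chosen after the data were seen.

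The steps were tested on simulated data. With known shrinkage, recovered SEs had a median ratio of 1.00 to the true ones for GSK-LSD1 at 2 days. The simulated dispersions kept most true SEs at means of at least 50 below the prior SD, where the smaller solution is right. That ratio therefore hardly tests the choice of solution. Of 200 genes with an added difference, those changed by log2 2 at a mean of at least 50 were found in 98.8% for GSK-LSD1 against 2-PCPA (13842 genes), 96.6% for 6 against 2 days (13053 genes) and 90.5% for siLSD1 against GSK-LSD1 at 6 days (13991 genes), with 7, 6 and 5 false calls. The simulated differences took the recovered SEs as true, so these rates hardly test the choice between the 2 solutions. When both solutions had to pass, 20.0% and 16.1% were found in the first 2, so that test misses most real differences of this size. A shifted list was found in 18 of 20 simulations for GSK-LSD1 at 2 days, 20 for 2-PCPA, 20 for GSK-LSD1 at 6 days and 18 for siLSD1. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used. Alternatives were a threshold of 0.01, a minimum absolute log2 change of 1, other filters on the mean, recentring on the median, other list statistics and those named above.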

Results

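RNA sequencing was performed on cultured human epidermal keratinocytes, the main cell type of the epidermis, after inhibition or knockdown of LSD1. LSD1, encoded by KDM1A, is a flavin-dependent histone demethylase that acts within repressor complexes. The series held 22 libraries of poly(A)-selected, strand-specific RNA in 8 groups. At 2 days, 3 libraries each were treated with water, 100 µM 2-PCPA, DMSO or 2 µM GSK-LSD1, and the same 3 cultures supplied all 4 arms. At 6 days, 3 libraries each were treated with DMSO or 2 µM GSK-LSD1 in other cultures, and the same 3 cultures supplied both arms. For the knockdown, 2 libraries each received 500 nM control siRNA (siCTL) or siRNA against LSD1 (siLSD1) and were harvested after 72 h. The same 2 cultures supplied both siRNA arms. 2-PCPA is tranylcypromine, which also inhibits monoamine oxidases, and GSK-LSD1 is named as an LSD1 inhibitor in the labels. The values used were 1 table per comparison of mean normalized counts, log2 fold changes, standard errors (SE) and adjusted p-values. Counts of genes and of list members below come from these tables, and depth per library was not analysed here. Largest changes below are those among genes with a mean of at least 50 and within the limits on symbols given above. The mean normalized counts summed to 30951038 for GSK-LSD1 at 2 days, 32066178 for 2-PCPA, 33333935 for GSK-LSD1 at 6 days and 39701056 for siLSD1. The fold changes of both 2 day tables were shrunken towards 0 by the authors' processing, so large changes at 2 days were understated.

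KDM1A was examined first, as a check of the labels. In the authors' deposited table for siLSD1, KDM1A fell by 3.00 on the log2 scale (SE 0.19, adjusted p = 3.2e-54), leaving 12.5% of the control level (95% interval 9.69% to 16.1%). Its log2 change in the authors' deposited tables was 0.03 (SE 0.08) with GSK-LSD1 at 2 days, -0.07 (SE 0.08) with 2-PCPA and -0.03 (SE 0.07) with GSK-LSD1 at 6 days, and none of these 3 passed the test.

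The first comparison asked which transcripts changed after 2 days of GSK-LSD1 against DMSO. Lists of keratinocyte differentiation genes rose, while those of interferon-stimulated and antigen presentation genes fell, and several matrix genes were among the largest decreases. The largest increases in the authors' deposited table were in MYO5C, a class V myosin (log2 3.75, SE 0.16), KRT80, a keratin of differentiating epithelia (3.54, SE 0.15), SCNN1A, a subunit of the epithelial sodium channel (3.47, SE 0.13), and CYFIP2, a WAVE complex member (3.35, SE 0.14). CAPN8 (3.31, SE 0.18), CHST6 (3.19, SE 0.12), SORT1 (3.17, SE 0.15) and ARFGEF3 (3.03, SE 0.19) followed in the authors' deposited table. The largest decreases in the authors' deposited table were in COL5A1, a type V collagen chain (-1.54, SE 0.15), VCAN, the proteoglycan versican (-1.50, SE 0.14), IL7R, a cytokine receptor (-1.48, SE 0.16), and MMP2, a gelatinase (-1.38, SE 0.13). CSPG4 (-1.33), POSTN (-1.15), TGM2 (-1.15) and CDH11 (-1.14) also fell, with adjusted p between 7.0e-19 and 9.9e-08 in the authors' deposited table. In all, 863 genes were higher and 350 lower among the 13954 tested in the authors' deposited table, and 204 of the higher and 14 of the lower ones changed by at least 1 on the shrunken log2 scale.

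Of the gene lists, the cornified envelope and late differentiation list rose with GSK-LSD1 at 2 days (cameraPR adjusted p = 1.0e-17). Of its 27 measured members, 14 were higher and none lower in the authors' deposited table, and 17 were higher when adjusted over the list alone. SPRR1B, a cornified envelope precursor (1.64, SE 0.14), PPL, the cytolinker periplakin (1.56, SE 0.13), and KLK7, a protease of desquamation (1.39, SE 0.13), led it in the authors' deposited table. The spinous and early differentiation list rose as well (adjusted p = 3.1e-17), with 13 of 23 members higher and 14 adjusted over the list alone, among them the tight junction gene CLDN4 (1.70, SE 0.15 in the authors' deposited table). Epidermal fate transcription factors rose (adjusted p = 1.1e-05), with 10 of 36 higher and 15 higher and 1 lower adjusted over the list alone. The authors' deposited table gave 1.70 (SE 0.14) for OVOL2, 1.45 (SE 0.17) for GRHL1 and 0.88 (SE 0.12) for KLF4. Lipid barrier genes (6 of 22 higher, adjusted p = 1.3e-04), wound and stress keratins (4 of 5, 2.8e-05), simple epithelial keratins (2 of 4, 1.3e-13) and antimicrobial and alarmin genes (7 of 18, 4.2e-04) also rose. Adjusted over the list alone, these 4 lists had 6, 5, 3 and 9 members higher, and 1 lower in the lipid and antimicrobial lists. SULT2B1, which sulfates cholesterol (1.89, SE 0.19), ABCA12, a lipid transporter of lamellar granules (1.06, SE 0.13), KRT8 (adjusted p = 1.5e-63), KRT18 (1.25, SE 0.10) and IL1RN, the interleukin 1 receptor antagonist (1.12, SE 0.16), were among them in the authors' deposited table. KRT6B rose by 1.05 (SE 0.14) in the authors' deposited table, but KRT6A, KRT6B and KRT6C are near-identical copies, so their separate values are uncertain.

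Interferon-stimulated genes fell with GSK-LSD1 at 2 days (9 of 39 lower, 12 adjusted over the list alone, cameraPR adjusted p = 7.2e-05), led by MX2 (-0.62, SE 0.12) and SAMD9L (-0.60, SE 0.12) in the authors' deposited table. Antigen presentation genes fell (2 of 15, 3 adjusted over the list alone, adjusted p = 0.0066), with HLA-B at -0.40 (SE 0.11) and HLA-C at -0.29 (SE 0.09) in the authors' deposited table. HLA class I genes are similar in sequence, so reads between them are uncertain. The dermal fibroblast list fell (3 of 7, 5 adjusted over the list alone, adjusted p = 4.5e-06), with THY1 at -0.95 (SE 0.15) beside COL5A1 in the authors' deposited table. In the TGF-beta and mesenchymal list 5 of 21 members were lower and 4 higher (7 and 4 adjusted over the list alone, adjusted p = 0.030, down). MMP2 and SPARC (-0.81, SE 0.09) were lower in the authors' deposited table, while the transcription factors SNAI2 (0.95, SE 0.09) and ZEB1 (1.14, SE 0.19) and the cadherin CDH2 (1.58, SE 0.19) were higher. The TGF-beta list did not pass with a preset correlation of 0.05 (adjusted p = 0.13), with ranks (0.073) or with log2 fold change as the statistic (0.14). The remaining lists did not pass, including basal progenitor and adhesion genes (adjusted p = 0.57), cell cycle genes (0.12) and p53 targets (0.76).

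The second comparison asked the same of 2-PCPA against water at 2 days. The genes that rose most in the authors' deposited table were MYO5C (4.23, SE 0.15), KRT80 (4.01, SE 0.10), ARFGEF3 (3.74, SE 0.17) and CYFIP2 (3.59, SE 0.12), followed by GGT6 (3.08), CHST6 (3.06), ABCA3, a lipid transporter (3.05), and TMEM125 (2.98). COL5A1 (-1.86, SE 0.13), VCAN (-1.65, SE 0.14), IL7R (-1.53, SE 0.15) and MMP2 (-1.48, SE 0.11) fell most in the authors' deposited table. CSPG4 (-1.46), NACAD (-1.34), POSTN (-1.31) and THY1 (-1.19) fell with adjusted p between 3.8e-30 and 6.9e-10 in the authors' deposited table. In total 1161 genes were higher and 559 lower among 13992 tested in the authors' deposited table, of which 236 and 20 changed by at least 1 on the shrunken log2 scale.

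The cornified envelope list rose with 2-PCPA (19 of 28 higher, 20 adjusted over the list alone, cameraPR adjusted p = 2.3e-25). PPL (1.79, SE 0.08), SPRR1B (1.95, SE 0.11) and IVL, the envelope precursor involucrin (1.81, SE 0.12), had the lowest p in the authors' deposited table. The spinous list rose (13 of 23, adjusted p = 3.6e-18), as did the fate transcription factors (15 of 35 higher and 1 lower, adjusted p = 1.5e-10). Adjusted over the list alone the counts were 15 higher and 2 lower for the spinous list and 17 and 1 for the fate list. GRHL3 rose by 2.16 (SE 0.12), ZNF750 by 2.00 (SE 0.17) and OVOL2 by 1.74 (SE 0.13), while MAF fell by 0.59 (SE 0.19), in the authors' deposited table. Lipid barrier genes (9 of 22 higher and 1 lower, adjusted p = 1.4e-05), wound keratins (2 of 5, 0.0017), simple keratins (2 of 4, 6.4e-12) and antimicrobial genes (9 of 17, 2.1e-10) rose. Adjusted over the list alone they had 10, 3, 2 and 11 members higher. The calprotectin subunits S100A9 (1.70, SE 0.11) and S100A8 (1.57, SE 0.15) were among them in the authors' deposited table. The EGFR and MAPK response list rose (8 of 22, 8 adjusted over the list alone, adjusted p = 4.2e-04), with FOS at 0.66 (SE 0.10) and the ligand EREG at 0.53 (SE 0.10) in the authors' deposited table.

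Interferon-stimulated genes (12 of 39 lower, adjusted p = 2.3e-06), antigen presentation genes (7 of 15, 4.5e-06) and the dermal fibroblast list (5 of 7, 7.3e-07) fell with 2-PCPA. Adjusted over the list alone, 19, 10 and 5 members were lower. MX2 stood at -0.76 (SE 0.13), the proteasome subunit PSMB9 at -0.53 (SE 0.11) and HLA-B at -0.49 (SE 0.08) in the authors' deposited table. The TGF-beta and mesenchymal list fell (8 lower and 4 higher of 21, 9 and 4 adjusted over the list alone, adjusted p = 0.0088), again with SNAI2 (1.08, SE 0.08) higher in the authors' deposited table. The cell cycle list fell by a small amount (median log2 -0.11, adjusted p = 0.0059), with only TK1 (-0.33) and BIRC5 (-0.25) lower and E2F2 (0.61) higher of its 44 members in the authors' deposited table, 2 and 1 adjusted over the list alone. With a preset correlation of 0.05 neither of these 2 lists passed (adjusted p = 0.059 for TGF-beta and 0.087 for the cell cycle), nor with log2 fold change as the statistic (0.063 and 0.070). With ranks the TGF-beta and simple keratin lists did not pass (0.084 and 0.18).

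The compounds were next compared at 2 days, at 2 µM GSK-LSD1 and 100 µM 2-PCPA, so time was matched and dose was not. Of the genes tested in both of the authors' deposited tables, 777 were higher with both compounds where 72.0 were expected of independent lists, and 271 were lower with both where 14.1 were expected. No gene was called in opposite directions, and log2 changes correlated across 11950 genes (Pearson r 0.90, Spearman rho 0.74), which are not independent replicates. KRT8, a keratin of simple epithelia, rose with both (1.48, SE 0.07 with 2-PCPA), and CHRNB1, an acetylcholine receptor subunit, stood at 1.86 (SE 0.09) and 1.71 (SE 0.08), in the authors' deposited tables. To test differences, unshrunken values were recovered from the authors' deposited tables. On that scale 2 of 13842 genes were higher with GSK-LSD1. CAPN8 differed by 3.45 on the log2 scale (95% interval 2.78 to 4.12) and NOTCH3, a Notch receptor, by 2.08 (1.40 to 2.76). A further 9 genes were higher with 2-PCPA: BSPRY (difference -3.04, 95% interval -3.85 to -2.23), COBL, an actin nucleator (-2.78, -3.41 to -2.14), KCNJ11, a potassium channel (-2.49, -3.41 to -1.57), PADI2 (-2.24, -3.12 to -1.35) and the tight junction gene CLDN1 (-1.87, -2.60 to -1.14). The other 4, named after their values were seen, were GRHL3 (-1.62), S100A8 (-1.65), S100A9 (-1.23) and SBSN (-1.28). Each shrunken SE has a pair of possible unshrunken values, and no gene passed when both had to pass, with 39 genes at unadjusted p below 0.05 against 96 in the main test. With the other solution NOTCH3 even turned in sign (-0.38). On the scale as deposited 3 genes were higher and 12 lower, and KCNJ11 no longer passed (difference -1.03, z test adjusted p = 0.089). For genes with a mean of at least 50, the 95% interval of a difference reached a median of 0.34 to either side. The 96 genes at unadjusted p below 0.05 are fewer than 0.05 of the 13842 tested, the share expected when nothing differs. The z test was therefore conservative here, and its few calls and its intervals do not measure how alike the compounds were.

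The third comparison asked what 6 days of GSK-LSD1 changed against 6 days of DMSO. Differentiation genes again rose, here on the unshrunken scale of the authors' deposited table. SBSN, suprabasin (6.14, SE 0.19), DSG1, the desmosomal cadherin desmoglein 1 (5.94, SE 0.24), PI3, the protease inhibitor elafin (6.16, SE 0.23), and NOTCH3 (6.35, SE 0.19) all rose. The largest fitted increases in the authors' deposited table were in BSPRY (13.01, SE 1.19), NUP210, a nuclear pore protein (12.50, SE 1.31), TBC1D3C (11.11, SE 3.84), SLC6A14, an amino acid transporter (9.62, SE 1.74), MAL (8.96, SE 2.04), DEGS2, a sphingolipid hydroxylase (8.80, SE 1.04), SLC27A2 (7.80, SE 0.81) and CEACAM6 (7.38, SE 1.12). For all of these except SLC27A2 the control level was below 1 normalized count in the authors' deposited table (0.18 for BSPRY and 0.35 for NUP210), so the folds depend on the fit. TBC1D3C belongs to a family of near-identical copies and is uncertain. The largest decreases in the authors' deposited table were in POSTN, the matrix protein periostin (-6.52, SE 0.76), CPED1 (-4.43, SE 1.35), VCAN (-4.30, SE 0.24), MEIS3 (-3.98, SE 1.42), CDH11, a mesenchymal cadherin (-3.92, SE 0.30), COL5A1 (-3.80, SE 0.37), THY1 (-3.64, SE 0.72) and HAS2, a hyaluronan synthase (-3.36, SE 0.42). Among 15397 genes tested, 1678 were higher and 1377 lower in the authors' deposited table, 737 and 327 of them by at least 1 on the log2 scale.

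At 6 days the cornified envelope list rose (27 of 39 higher, 30 adjusted over the list alone, cameraPR adjusted p = 1.5e-39, median log2 3.38), with SPRR1B at 4.91 (SE 0.10) and KLK7 at 4.31 (SE 0.15) in the authors' deposited table. The spinous list (20 of 24, 20 adjusted over the list alone, 1.8e-49) and the fate transcription factors (18 higher and 1 lower of 36, 21 and 2 adjusted over the list alone, 3.2e-17) rose too. OVOL1 rose by 5.55 (SE 0.21), ZNF750 by 4.97 (SE 0.25) and GRHL3 by 3.63 (SE 0.15) in the authors' deposited table. Lipid barrier genes (12 higher and 2 lower of 24, 4.5e-07), wound keratins (5 of 5, 1.7e-22), simple keratins (3 of 4, 3.3e-04) and antimicrobial genes (12 higher and 3 lower of 20, 1.4e-22) rose. Adjusted over the list alone, 16, 5, 3 and 12 were higher. SULT2B1 (5.40, SE 0.24), KRT6B (2.85, SE 0.08), KRT18 (1.22, SE 0.12), SLPI, a secreted protease inhibitor (5.97, SE 0.22), and S100A9 (4.03, SE 0.13) rose, while IL1A (-0.69, SE 0.09) and the NF-kappaB inhibitor TNFAIP3 (-1.11, SE 0.15) fell, in the authors' deposited table. The Notch list passed upward (5 higher and 2 lower of 17, 7 and 2 adjusted over the list alone, 0.0029). Its mean was 0.71 but its median -0.07, since NOTCH3 and NRARP (2.12, SE 0.29) were higher and the ligand JAG1 (-0.61, SE 0.07) lower in the authors' deposited table. With ranks as the statistic the Notch list did not pass (adjusted p = 0.57).

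Of the lists that fell at 6 days, the TGF-beta and mesenchymal list had 13 lower and 4 higher of 21 (14 and 4 adjusted over the list alone, cameraPR adjusted p = 1.4e-06). FN1, fibronectin (-1.52, SE 0.07), and MMP2 (-2.64, SE 0.18) fell, while SNAI2 (1.25, SE 0.08) and CDH2 (3.16, SE 0.44) rose, in the authors' deposited table. Antigen presentation genes (7 of 14 lower, 8 adjusted over the list alone, 1.2e-04), unfolded protein and amino acid stress genes (8 of 18, 8 adjusted over the list alone, 4.4e-04) and the dermal fibroblast list (6 of 10, 8 adjusted over the list alone, 1.2e-04) fell. HLA-B fell (adjusted p = 4.1e-10), the chaperone HSPA5 stood at -0.82 (SE 0.07) and COL1A2 at -3.55 (SE 0.61) in the authors' deposited table. Interferon-stimulated genes (11 lower and 2 higher of 40, 13 and 2 adjusted over the list alone, 0.0066) and basal progenitor and adhesion genes (8 lower and 5 higher of 24, 9 and 5 adjusted over the list alone, 0.013) fell. MX2 (-0.90, SE 0.14), the matrix protein TNC (-1.74, SE 0.10) and the laminin chain LAMA3 (-0.65, SE 0.07) fell, while KRT15, a basal keratin (2.08, SE 0.30), rose, in the authors' deposited table. The last 2 lists did not pass with a preset correlation of 0.05 (adjusted p = 0.081 for both), nor the basal list with ranks (0.25), and with log2 fold change as the statistic the interferon, basal, antigen presentation, stress and TGF-beta lists did not pass (adjusted p between 0.070 and 0.15). The cell cycle list did not pass (adjusted p = 0.62).

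Changes at 6 days were then set against those at 2 days for GSK-LSD1. The calls overlapped: 755 genes were higher at both times where 95.8 were expected, and 322 lower where 33.9 were expected, in the authors' deposited tables. Only MAP1B, a microtubule-associated protein, was called in opposite directions (0.31, SE 0.10 at 2 days and -0.49, SE 0.12 at 6 days in the authors' deposited tables), a gene singled out after its values were seen. On the recovered scale 143 of 13053 genes were higher at 6 days than at 2 days and 84 lower. The cornified envelope list had 12 of 27 members and the spinous list 12 of 23 members higher at 6 days, with median differences of 2.10 and 0.76 on that scale. The antimicrobial list had 9 higher and 2 lower of 17. SBSN rose more at 6 days by 5.74 (95% interval 5.17 to 6.32), and COL5A1 fell further by a difference of -1.94 (-2.74 to -1.14). On the 2 day scale as deposited 359 were higher and 192 lower, and when both unshrunken solutions had to pass, 40 were higher and 2 lower. With the other solution 47 of the 143 higher and 66 of the 84 lower genes would differ in the opposite direction, COL5A1 among them (5.27). Of the list members above, that held for 7 of the 12 cornified envelope genes, 2 of the 12 spinous genes, and 1 of the 9 higher and 2 of the 2 lower antimicrobial genes, while 2, 7, 3 and 0 passed with both solutions. The direction of most lower differences and of part of the higher ones therefore rests on the choice of solution. The 2 times used different cultures and separately made tables, so time cannot be told apart from culture or library batch.

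The fourth comparison asked what loss of LSD1 by siRNA changed after 72 h. KRT80 (2.41, SE 0.30), CHST6 (2.61, SE 0.39), TMEM125 (2.57, SE 0.39) and KRT8 (1.25, SE 0.19) rose in the authors' deposited table, as they did with both inhibitors. Other large increases in the authors' deposited table were in SYT15 (3.43, SE 0.59), ASTN2 (3.64, SE 0.91), DMC1, a meiotic recombinase (3.31, SE 0.75), and STEAP2, a metalloreductase (3.12, SE 0.37). GCOM1 (4.29, SE 0.53) and HTD2 (3.76, SE 1.06) rose in the authors' deposited table, but both share exons with neighbouring genes and are uncertain. Besides KDM1A, the largest decreases in the authors' deposited table were in NIPSNAP3B (-5.00, SE 0.93), FAM156A (-4.26, SE 0.82, a gene with a near-identical copy and so uncertain), TPGS1 (-3.67, SE 0.96), MROH8 (-3.51, SE 0.37), COL9A3 (-3.21, SE 0.74), ANKRD46 (-2.45, SE 0.47) and ABHD16B (-2.23, SE 0.52). In total 59 genes were higher and 281 lower among 15136 tested in the authors' deposited table, 42 and 96 of them by at least 1. The lower genes had a median transcript GC content of 64.0%, against 49.0% for all genes tested, and the log2 change fell with GC content across 12771 genes (Spearman rho -0.44). After trends on GC content and transcript length were removed, 51 genes were higher and 61 lower, so the share of higher genes moved from 17.4% to 45.5%. KDM1A (-3.01), KRT80 (2.54), STEAP2 (2.93) and MROH8 (-3.53) still passed, whereas HTD2 (3.74), TPGS1 (-3.06), COL9A3 (-2.61) and ABHD16B (-1.62) did not (adjusted p between 0.053 and 0.14), although their changes stayed large beside SEs of 1.06, 0.96, 0.74 and 0.52.

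With siLSD1 the cornified envelope list rose (4 of 27 higher, 6 adjusted over the list alone, cameraPR adjusted p = 4.7e-04), with PPL (0.70, SE 0.15), CSTA, cystatin A (0.86, SE 0.22), and SPRR1A (1.21, SE 0.32) higher in the authors' deposited table. The spinous list rose (2 of 23 higher, 6 higher and 1 lower adjusted over the list alone, 1.6e-04), with DSG1 at 1.87 (SE 0.46) in the authors' deposited table. Simple keratins (1 of 4, 2 adjusted over the list alone, 5.2e-04), antimicrobial genes (1 of 14, 1 adjusted over the list alone, 0.028) and interferon-stimulated genes (1 higher and 1 lower of 39, 2 and 1 adjusted over the list alone, 4.7e-04) passed upward. IFI44L rose by 0.88 (SE 0.22) and ISG15 fell by 0.66 (SE 0.19) in the authors' deposited table. Antigen presentation genes (3 of 14 lower, 4 adjusted over the list alone, 8.3e-04), unfolded protein and amino acid stress genes (3 of 18, 3 adjusted over the list alone, 5.2e-04) and cholesterol synthesis genes (2 of 24, 2 adjusted over the list alone, 0.0051) fell. HLA-B (-0.83, SE 0.15), HERPUD1, an endoplasmic reticulum stress gene (-0.77, SE 0.20), and MVD, a mevalonate pathway enzyme (-1.06, SE 0.15), were lower in the authors' deposited table. These 8 lists also passed after the GC and length trends were removed (adjusted p between 1.7e-10 and 0.019), as did wound keratins (1.6e-05 against 0.053 before) and fate transcription factors (0.033 against 0.10, upward), although MVD (0.10), CSTA (0.081), IFI44L (0.093), HLA-C (0.052) and ISG15 (1) did not. The corrected change was -0.51 for MVD and -0.25 for ISG15, but 0.74 for CSTA, 0.72 for IFI44L and -0.55 for HLA-C, and CSTA and IFI44L moved by less than their SE of 0.22. None passed with log2 fold change as the statistic (adjusted p between 0.11 and 0.99), the antimicrobial and cholesterol lists not with a preset correlation of 0.05 (0.089 and 0.058), and the simple keratin, antimicrobial and antigen presentation lists not with ranks (0.17, 0.055 and 0.055).

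siLSD1 was compared with GSK-LSD1 at 6 days as the difference of their log2 changes. Of 13991 genes tested, 201 were higher and 362 lower with siLSD1. Differentiation genes made up part of the lower ones: 14 of 26 members of the cornified envelope list, 13 of 23 of the spinous list and 4 of 5 wound keratins were lower with siLSD1, and none higher. SBSN differed by -6.01 (95% interval -6.66 to -5.36), PI3 by -5.65 (-6.43 to -4.86), NOTCH3 by -5.59 (-6.36 to -4.82), SGPP2, a sphingosine phosphatase, by -5.92 (-7.01 to -4.82) and IGFL2 by -6.11 (-9.27 to -2.95). Higher with siLSD1 were GCOM1 (5.50, 4.35 to 6.64), CPED1 (7.24, 3.94 to 10.55), THY1 (4.30, 2.64 to 5.96), SYT11 (3.92, 2.33 to 5.50) and SLX1B (17.37, 7.57 to 27.16), the last from a pair of near-identical genes and uncertain. Interferon-stimulated genes were higher with siLSD1 in 5 of 39 members and lower in none. Cultures, exposure times and the GC trend also differed between the 2 tables, so these differences are not those of the intervention alone. Removing the GC and length trends kept the numbers of genes higher and lower within 1.5 times.

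The remaining lists gave fewer changes. Among neuronal genes, which LSD1 complexes with REST can repress, UCHL1, a ubiquitin hydrolase, rose by 2.36 (SE 0.17) with GSK-LSD1 at 2 days, 2.69 (SE 0.15) with 2-PCPA and 3.98 (SE 0.35) at 6 days in the authors' deposited tables. NEFH, a neurofilament chain, was higher in the same 3 of the authors' deposited tables (0.63, 0.85 and 1.37), while NEFL (-0.60, -0.57 and -2.51), the sodium channel SCN2A (-0.73, -0.85 and -3.29) and the vesicle protein SYT1 (-0.69, -0.76 and -1.87) were lower. The list as a whole did not pass in any comparison (2 higher and 3 lower of 13, 3 and 3 of 13, 4 and 5 of 15, and 0 of 17 with siLSD1; cameraPR adjusted p 0.77, 0.28, 0.54 and 0.71). Adjusted over the list alone the calls were 2 and 3, 4 and 5, 4 and 5, and 0 with siLSD1.

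Of the cholesterol synthesis genes, the sterol reductase TM7SF2 rose with all 3 inhibitor treatments (1.96, SE 0.12; 1.82, SE 0.10; 2.34, SE 0.18) in the authors' deposited tables, while at 6 days INSIG1 (-0.61, SE 0.10) fell. That list did not pass with the inhibitors (adjusted p 0.25, 0.14 and 0.94). The NRF2 list did not pass (0.75, 0.14, 0.11 and 0.66 with siLSD1), although GCLC, a glutathione synthesis enzyme (0.66, SE 0.09), was higher and TXNRD1 (-0.28, SE 0.08) lower at 6 days in the authors' deposited table. In the WNT list (0.75, 0.96, 0.11 and 0.39), LEF1 fell with all 3 inhibitor treatments (-0.56, -0.58 and -1.22) in the authors' deposited tables, while WNT7B rose with both inhibitors at 2 days. In the LSD1 complex list (0.80, 0.96 and 0.62 with the inhibitors; with siLSD1 it holds the knocked-down KDM1A itself, so its test, 0.14 and 0.023 after trend removal, says nothing further), the demethylase KDM6A fell (-0.68, SE 0.10) and the corepressor RCOR1 rose (0.32, SE 0.10) at 6 days in the authors' deposited table. Amine handling genes did not pass (0.76, 0.60, 0.94 and 0.059); the lysyl oxidase LOXL1 was higher with all 3 inhibitor treatments (0.71, 0.57 and 0.95) and SAT1 with 2-PCPA (0.23), while LOXL2 was lower with GSK-LSD1 at 2 days (-0.56), at 6 days (-1.86) and with siLSD1 (-0.95) in the authors' deposited tables.

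Markers of other cell types were few. The melanocyte list did not pass (0.22, 0.087, 0.11 and 0.85), but passed upward with ranks for the 3 inhibitor treatments (0.048, 0.015 and 0.037) and with log2 fold change as the statistic for 2-PCPA (0.031) and at 6 days (2.8e-07). MITF, a melanocyte transcription factor, was higher with 2-PCPA (0.50, SE 0.17) and at 6 days (0.73, SE 0.27) in the authors' deposited tables, with KIT, a receptor also of other cells, higher with all 3 inhibitor treatments at means of 12.9, 13.2 and 30.2 normalized counts in the authors' deposited tables. The myeloid list (0.12, 0.18, 0.076 and 0.92) had VCAN as its only lower gene in the authors' deposited tables, which matrix-producing cells also express, and the Merkel list (0.98, 0.96, 0.77 and 0.46) had 2 measured members. At most 1 endothelial and 1 lymphoid or Langerhans member was tested in any table, so these lists had no test. The p53 list did not pass (0.76, 0.87, 0.11 and 0.053), with 5 of 22 members lower at 6 days, among them the receptor TNFRSF10B (-0.38, SE 0.08) in the authors' deposited table. Unfolded protein stress genes did not pass at 2 days (0.16 and 0.19), nor did Notch genes at 2 days or with siLSD1 (0.11, 0.36 and 0.069), or EGFR and MAPK response genes with GSK-LSD1 at 2 days, at 6 days or with siLSD1 (0.17, 0.53 and 0.88). Basal genes did not pass with 2-PCPA or siLSD1 (0.82 and 0.71). With ranks some of these lists passed: cell cycle (0.028, down) and EGFR genes (0.010, up) with GSK-LSD1 at 2 days, NRF2 (0.0061, up) and unfolded protein stress genes (0.012, up) with 2-PCPA, and p53 (0.015, down) and amine handling genes (0.050, down) with siLSD1. Log2 fold change as the statistic did so for Notch genes with GSK-LSD1 at 2 days (0.019, up) and myeloid genes at 6 days (0.011, down). With siLSD1 the cell cycle (0.88), lipid barrier (0.099), TGF-beta (0.32) and dermal fibroblast (0.66) lists did not pass either.

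Among lists that did not pass, the median, the mean and the direction of the test differed in sign for some. The neuronal list had a negative median and a positive mean at 2 days (-0.19 and 0.05 with GSK-LSD1, -0.16 and 0.09 with 2-PCPA), with the test upward. The same held in part for the myeloid list in 3 comparisons, for amine handling (0.17 and -0.09, upward) and cell cycle genes (-0.04 and 0.02, downward) at 6 days, and for NRF2, LSD1 complex, melanocyte and dermal fibroblast genes with siLSD1. The p53 and LSD1 complex lists at 2 days and the WNT list with 2-PCPA differed in sign with medians near 0, as did the Merkel list with all 3 inhibitor treatments.

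Calls were last compared across all 4 tables. Among 12934 genes tested in each of the authors' deposited tables, 29 were higher and 6 lower in all 4, where 4 independent lists would share 0.03 in each direction. The inhibitor lists were far from independent, with 659 genes higher and 257 lower in all 3 inhibitor comparisons. The value of 0.03 therefore does not show that siLSD1 shared more with them than expected, which only the pairwise overlaps below address. CLDN7, a claudin, was higher by 2.31 and 2.21 at 2 days, 3.53 at 6 days and 1.69 with siLSD1 (SE 0.09 to 0.29), and SNAI2 by 0.95, 1.08, 1.25 and 1.03, in the authors' deposited tables. CHRNB1, A2ML1, a protease inhibitor, AMOT, a junction scaffold, and PPL were also higher in all 4 of the authors' deposited tables. HLA-B, HLA-C, IGFBP4, an insulin-like growth factor binding protein, ZFP36L2, an mRNA decay factor, MAMDC2 and P3H3, a collagen prolyl hydroxylase, made up the 6 lower genes in the authors' deposited tables. The higher genes of siLSD1 overlapped those of GSK-LSD1 at 2 days (29 against 3.18 expected, Fisher exact test adjusted p = 5.6e-22), of 2-PCPA (35 against 4.17, 1.8e-26) and of GSK-LSD1 at 6 days (37 against 6.37, 1.3e-21). In the same order 6, 9 and 10 genes were called in opposite directions, and log2 changes correlated little across genes (Pearson r 0.20, 0.28 and 0.21; Spearman rho -0.0034, 0.18 and 0.19). Its lower genes overlapped those of GSK-LSD1 at 6 days (45 against 26.4, exact adjusted p = 3.1e-04) and of 2-PCPA (17 against 10.5, 0.039), but not those of GSK-LSD1 at 2 days (7 against 6.58, 0.49). Neither of the lower overlaps passed after the GC and length trends were removed (adjusted p = 0.46 and 0.83). The log2 change rose with GC content with GSK-LSD1 at 2 days (Spearman rho 0.31) and fell with it with siLSD1 (-0.44). These opposite trends also enter the rho of -0.0034 and the 7 shared lower genes, which thus do not show that a shared response is absent.

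**Figure D1:**
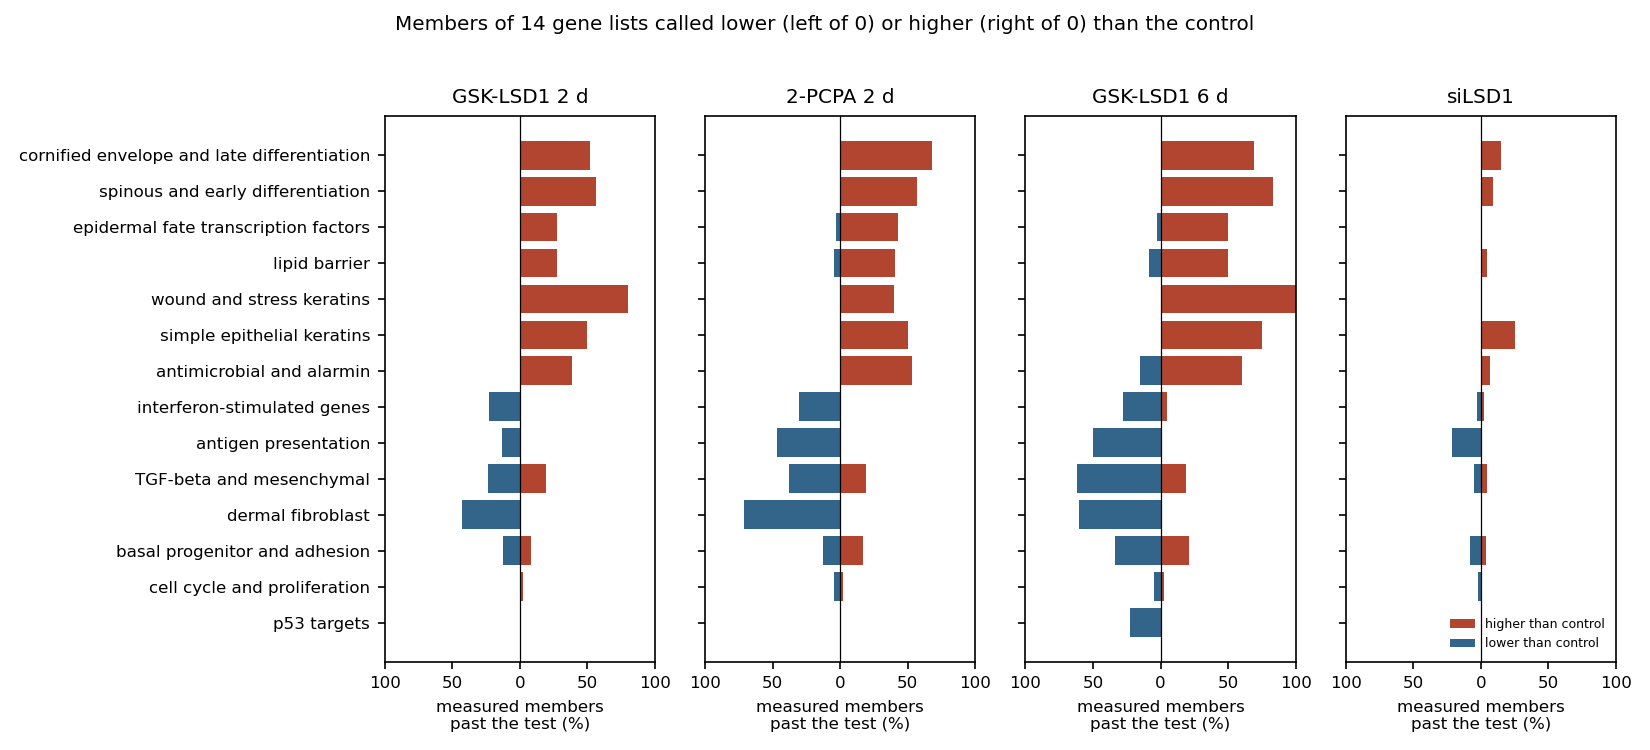
Share of the measured members of 14 gene lists, in percent on the horizontal axis, that passed the test as higher (right of 0) or lower (left of 0) than the control, 1 panel per comparison. Differentiation lists lie to the right with the inhibitors, with 27 of 39 cornified envelope members higher at 6 days, and the siLSD1 panel holds few calls.

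**Figure D2:**
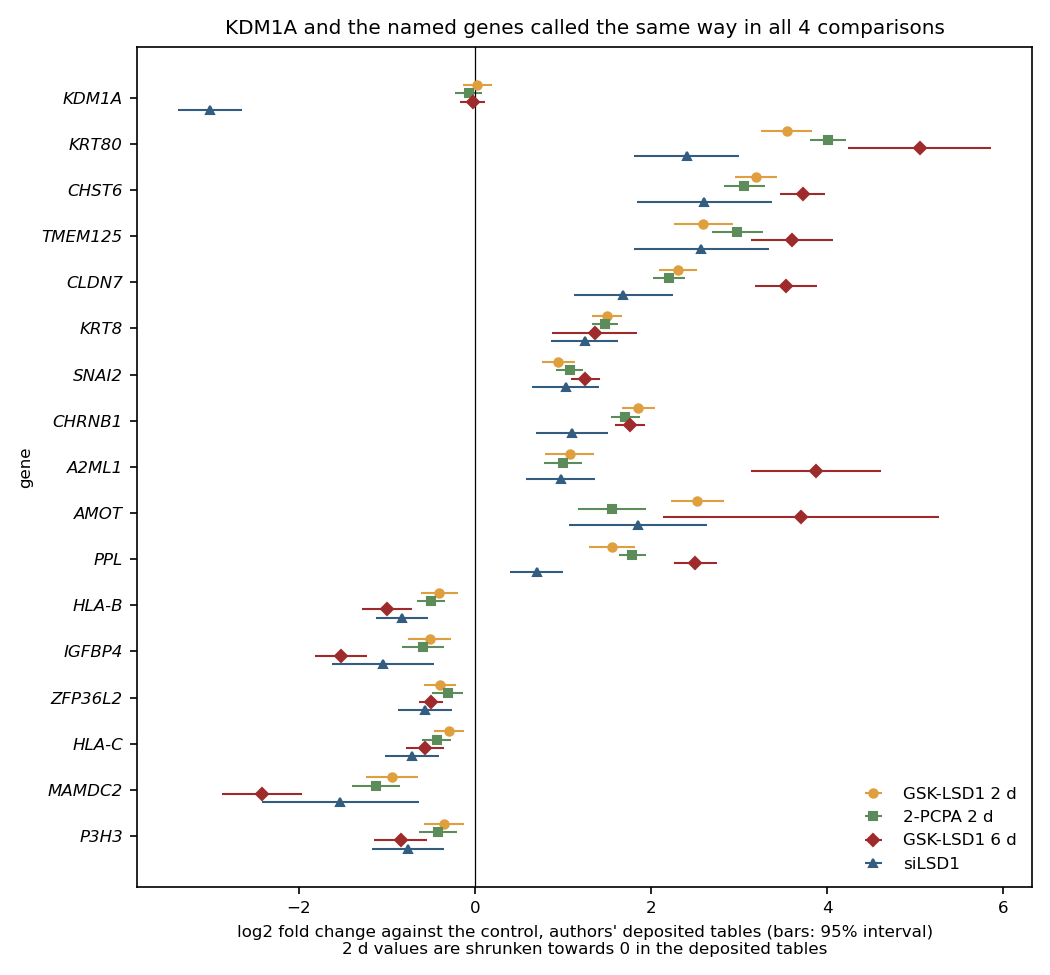
Log2 fold changes from the authors' deposited tables of KDM1A and of the named genes called in the same direction in all 4 comparisons, with bars for 95% intervals and 1 symbol per comparison. KDM1A stands at -3.00 with siLSD1 and near 0 with the inhibitors, and the 2 day values are shrunken towards 0.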

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

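The tests of off-centre normalization, of protein-coding genes without exon overlap, of fibroblast transcripts and of both unshrunken solutions were chosen only after the results were seen, as were the scale of the difference between 6 and 2 days and the stricter reading of both tests on the 8 genes below.

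The response to GSK-LSD1 differed between 6 and 2 days by a test of the difference itself, with 143 genes higher and 84 lower at 6 days on the recovered scale. Among genes with a mean of at least 50 in both tables, the largest differences upward were in BSPRY (12.01, SE 1.21), NUP210 (10.83, SE 1.34), SLC6A14 (7.98, SE 1.77), DEGS2 (5.86, SE 1.68) and SBSN (5.74, SE 0.29). BSPRY, NUP210, SLC6A14 and DEGS2 had 6 day control levels of 0.18, 0.35, 0.64 and 0.64 normalized counts, so the size of their differences depends on the fit. The largest downward were in POSTN (-4.56, SE 0.82), CDH11 (-2.59, SE 0.34), VCAN (-2.50, SE 0.29), HAS2 (-2.07, SE 0.49) and COL5A1 (-1.94, SE 0.41). When both unshrunken solutions had to pass, BSPRY, NUP210, SBSN and POSTN passed and the other 6 did not (adjusted p between 0.11 and 1). With the other solution the difference turned upward for CDH11 (3.92), VCAN (4.78) and COL5A1 (5.27), and in all the sign turned for 47 of the 143 higher and 66 of the 84 lower genes, whose direction rests on the choice of solution. The 2 times used different cultures, so time cannot be told apart from culture or batch.

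More genes were lower than higher with siLSD1, 281 against 59. Recentring left a ratio of lower to higher calls of 4.32 (268 against 62). The median log2 change it removed was only -0.010, so the calls could hardly move and it does not decide on an off-centre scale. Protein-coding genes without exon overlap gave 3.51 (130 against 37), which argues against read assignment at overlapping loci as the whole cause. After GC and length trends were removed the ratio was 1.20 (61 against 51), with 59 of the 281 lower and 39 of the 59 higher genes kept. The median log2 change of the 281 genes moved from -0.87 to -0.47 (median SE 0.20), so at the median the change shrank, while single genes such as COL9A3 (-3.21 to -2.61) lost their call with a large change left. A GC or length bias between libraries may therefore account for much of the excess of lower genes, although a biological response that follows GC content stays open.

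Matrix genes known from fibroblasts, such as COL5A1 and THY1, were lower with both inhibitors at 2 days. If fewer fibroblasts in the treated cultures were the cause, their abundant transcripts should exceed COL5A1, but the median mean of COL1A2, COL3A1, DCN and LUM was 2.12% of the COL5A1 mean in the GSK-LSD1 table and 1.45% in the 2-PCPA table (COL1A2 26.1, COL3A1 6.47, DCN 7.90 and LUM 1.26 against 338 with GSK-LSD1). The low levels of COL1A2, COL3A1, DCN and LUM argue against fibroblasts as the source, but COL1A1, outside this test, does not. Its mean was 327 against 338 for COL5A1 with GSK-LSD1, and 429 against 408 with 2-PCPA, where it exceeded COL5A1. The transcripts tested were chosen after the results were seen, so fewer fibroblasts cannot be excluded. Loss of LSD1 activity stays open: the 3 list members lower with both inhibitors had a median log2 change of -0.85 with siLSD1, with a 95% interval of -1.25 to 0.08. That interval came from redrawing the 3 changes by their SEs, so it does not hold the spread between genes or cultures. THY1 among them went the other way in the authors' deposited table (0.66, SE 0.44), the whole list had a median of 0.12, and COL5A1 stood at -0.69 (adjusted p = 0.37) after GC and length trends were removed.

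At 6 days, 8 genes with a mean of at least 50 rose from a control level below 1 normalized count, with SEs 2.23 to 13.4 times those of genes of like mean. Of these, 25.0% (2 of 8) had an exon overlapping another gene, against 41.0% of the others (one-sided Fisher exact p = 0.90), but the exact 95% interval of 3.19% to 65.1% is too wide to exclude shared reads. Uneven read assignment between libraries also stays open. The median ratio of SEs over 5 of these genes at 2 days was 1.17 with 2-PCPA and 1.36 with GSK-LSD1, below the 1.5 set beforehand. With the second solution for the shrunken SE it was 1.19 with 2-PCPA but 3.41 with GSK-LSD1. The prediction of a ratio above 2 in both 2 day tables thus failed with 2-PCPA under either solution, while GSK-LSD1 could not be decided. BSPRY, NUP210, SLC6A14 and DEGS2 had means of at least 50 at 2 days as well, with recovered log2 changes of only 1.00, 1.67, 1.64 and 2.93 with GSK-LSD1. Their 2 day DMSO levels were therefore well above 1 normalized count, so for these genes near silence was not seen in the 2 day DMSO cultures. The rest of the 8 genes and the siCTL levels were not examined in this way. A gene switched on from near silence at 6 days, which the treatment groups would allow, cannot be told apart from these explanations without values per library.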

How the results depend on the processing

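No paired analysis was possible because no values per library were used, and for the same reason a DESeq2 rerun with other size factors, the replicate block, leaving out each replicate and other splits of the libraries were not run. The GC and length correction, the exon overlap subset and the scales of the 2 day values were chosen after the data were seen. That correction was not run for the 2 differences with 2 day tables, although their GC trends differed. Spearman rho with GC content was 0.31 with GSK-LSD1 and -0.010 with 2-PCPA at 2 days, and 0.067 with GSK-LSD1 at 6 days. With the other solution for the unshrunken SE, 4 named differences turned in sign, NOTCH3 between compounds and CDH11, VCAN and COL5A1 between times (adjusted p = 1 each). Of all differences that passed, 1 of the 2 higher and 0 of the 9 lower between compounds, and 47 of 143 higher and 66 of 84 lower between times turned. Outside this setting no named gene or list that passed turned. Recentring kept each count of calls and of differences within 1.5 times, as did BH over all genes or over means of at least 10 for the calls in all 4 tables, and leaving out genes of large SE for the calls at 6 days and with siLSD1, where alone it was run. The median log2 changes as deposited lay between -0.017 and -0.010, so recentring could hardly move the counts.

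An adjusted p below 0.01 gave 210 lower genes with GSK-LSD1 at 2 days, 346 with 2-PCPA, 35 higher and 159 lower with siLSD1, 53 lower at 6 against 2 days, and 119 higher and 232 lower for siLSD1 against GSK-LSD1 at 6 days. An absolute log2 change of at least 1 left 204 higher and 14 lower with GSK-LSD1 at 2 days, 236 and 20 with 2-PCPA, 737 and 327 with GSK-LSD1 at 6 days, and 96 lower with siLSD1. Both settings are stricter by construction. Removing GC and length trends gave 61 lower genes with siLSD1, and protein-coding genes without exon overlap, a smaller set, gave 37 higher and 130 lower.

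Restricting the differences to genes called in at least 1 comparison, which tests fewer genes, gave 11 higher for GSK-LSD1 against 2-PCPA, 148 lower for 6 against 2 days, and 368 higher and 584 lower for siLSD1 against GSK-LSD1 at 6 days. The values as deposited gave 359 higher and 192 lower for 6 against 2 days. Requiring both solutions gave 40 and 2 there, and 0 higher and 0 lower for GSK-LSD1 against 2-PCPA (z test, 39 genes at unadjusted p below 0.05).

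The lower overlap of 2-PCPA and siLSD1 had adjusted p of 0.12 with the log2 minimum, 0.059 at means of at least 50 and 0.83 after trend removal, and that of GSK-LSD1 at 6 days and siLSD1 had 0.46 after trend removal. With a preset correlation of 0.05, 3 lists fell with 2-PCPA instead of 5. With log2 change as the statistic 3 fell with 2-PCPA, 2 with GSK-LSD1 at 6 days instead of 6 (1 of the 6 and the myeloid list), and with siLSD1 0 rose and 0 fell (cameraPR, 4 and 1 at unadjusted p below 0.05). With ranks 3 lists rose with siLSD1 instead of 5. The cause was not tested for the overlaps and list statistics. Of the single lists, 7 lost the threshold with the preset 0.05, 8 with ranks and 16 with log2 change, while 9 gained it with ranks and 4 with log2 change. Of the named differences, 9 lost it, 4 turned in sign and 4 kept it when both solutions had to pass.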
